A study of Mus musculus with 6 samples.

How the data were processed

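Stranded mRNA libraries were prepared from total RNA of mouse heart, per the labels' protocols, with 3 libraries from floxed and 3 from myocardial Gsdmd knockout mice given doxorubicin. The submitters' processing notes name fastp 0.19.3, HISAT2 2.1.0, StringTie 1.3.4d, Cufflinks, featureCounts 1.6.2, DESeq2 1.22.1 and GATK 4.0.11.0, and the genome build mm10, without saying which step each served. The authors deposited whole-number counts per gene for 35618 genes, which are not normalised, and FPKM values for 35606 of them. The 12 genes in the count table only had too few counts to be tested. For 2519 genes with high counts in every library, the deposited FPKM equalled the count divided by the library total and by 1 length per gene to within 0.451%. How reads that match several genes or the wrong strand were counted is not given in the sources used here, so genes with near-identical copies or overlapping neighbours have uncertain levels. The table gives gene positions, which are printed as they stand. The build of these positions is not given in the sources used here: of 35195 nuclear genes also present in GENCODE release M21, which is on the build that the notes name, 775 start at the same position, although 98.3% have the same span. No other value columns were present (0 of other samples).

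The libraries were grouped by genotype from the labels, and the single comparison was knockout minus floxed. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr at its minimum count of 10, which left 16591 genes holding 99.8% of the counts. Library sizes were scaled by TMM, and the quasi-likelihood F test was fitted with robust estimation and genotype as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes were obtained from the F statistic, and the 95% interval from its degrees of freedom. CPM values were computed with TMM-scaled library sizes. The common dispersion was 0.111, a biological coefficient of variation of 33.3%. With 3 libraries against 3, an exact permutation test of a single value cannot go below 0.1, so no such test is given.

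A total of 37 gene lists on ER stress, autophagy, cell death, heart muscle, metabolism, immunity and cell types were fixed before the data were examined, as were the tests and the alternatives. Of their entries 5 had no row in the table under that symbol. Lists with at least 5 tested members (34 of them) were compared with all other genes by camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Medians of the members' edgeR log2 fold changes are given as sizes. A list's level in a library is the median over its members of log2 CPM minus the mean of the floxed libraries. GO terms were taken from the table.

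The rule for named genes was fixed before the data were examined. Gsdmd and Retreg1 were always named. The 10 largest positive and 10 largest negative log2 fold changes were to be named among protein-coding genes past the threshold with a mean of at least 1 CPM in the higher group and no overlap between the genotypes, which gave Gsdmd and Tnnt3. For each list, up to 4 members past the threshold with the smallest p, or, where none passed, up to 2 with the smallest p, could be named as values. The rule selected 71 genes.

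The alternatives were RLE normalisation, no filter on low counts, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, limma on the deposited log2 FPKM with pseudocounts of 1 and 0.1 or with a mean FPKM of at least 1, the replicate number as a block, each library left out in turn, a log2 fold change of at least 1, camera with an estimated correlation, fry, and pathways from genes changed at least 2-fold. After the data were seen, library sizes without mitochondrially encoded genes and Gsdmd, edgeR without robust estimation, and camera over GO terms were added.

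The tests were tried on simulated counts of 16207 genes for this comparison, with the real means, library sizes and dispersions. edgeR recovered 8% of genes changed by 1 on the log2 scale, 72% of those changed by 2, 95.8% of those changed by 4 and 100% of those changed by 6, with 4 false calls among 143. DESeq2 recovered 28%, 90%, 97.9% and 100%, with 55 false calls among 226. Of 2 simulated lists of shifted genes, camera called 2 with the preset and 1 with an estimated correlation, and of 20 unshifted lists it called 0 either way. The simulated genes varied independently of one another, unlike those of the hearts. Figures were drawn with matplotlib 3.10.9.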

Results

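Transcript abundance was measured by RNA sequencing in 6 mouse heart samples collected 3 days after an intraperitoneal injection of 20 mg/kg doxorubicin, an anthracycline chemotherapy drug that damages the heart muscle. The mice were 6 to 8 weeks old. Of these libraries, 3 came from mice whose Gsdmd alleles were floxed, that is, flanked by recombination sites, and 3 came from mice in which Gsdmd was knocked out in the myocardium. Gsdmd encodes gasdermin D, the protein that forms pores in membranes during pyroptosis, an inflammatory form of cell death. Each library held between 17279147 and 18875902 counted reads. All 6 libraries carried at least 569 counts of the Y-linked gene Ddx3y and at most 6 counts of Xist. Pairs of libraries of one genotype correlated at 0.90 to 0.98 on log2 CPM, that is, counts scaled to library size, and pairs across the genotypes at 0.92 to 0.97, values taken across genes, which are not independent replicates. Mitochondrially encoded genes took 8.45%, 11.2% and 6.70% of the counts in the floxed libraries 1, 2 and 3, and 18.1%, 10.2% and 5.48% in the knockout libraries 1, 2 and 3. The labels do not say which animal each library came from, so the p-values measure the spread between these libraries. No hearts without doxorubicin were analysed here.

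The comparison of knockout with floxed hearts asked which transcripts depended on myocardial Gsdmd after doxorubicin, with endoplasmic reticulum (ER) stress, autophagy and apoptosis named as the processes of interest. The targeted gene was examined first. Gsdmd (ENSMUSG00000022575, chromosome 15, 75734176 to 75739257, plus strand, at the positions the deposited table gives) averaged 7613 ± 811 CPM (SD, n = 3) in the floxed libraries and 108 ± 29.7 CPM (SD, n = 3) in the knockout libraries. This was 70.2-fold lower, a log2 fold change of -6.13 with a standard error of 0.37 and an adjusted p of 0.0104 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 3 floxed libraries held 129118, 137849 and 144568 Gsdmd counts and the 3 knockout libraries 1220, 2608 and 2228, so Gsdmd divided the libraries as their labels do. In the floxed libraries Gsdmd ranked between 5 and 6 among all genes by count and took 0.688% to 0.794% of the reads, and the deposited FPKM averaged 3179 ± 246 (SD, n = 3) there against 46.3 ± 14.8 (SD, n = 3). Whole hearts also hold cells outside the knockout, and a count over the whole gene does not show which exons the knockout transcripts lacked.

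One further gene passed the test. Tnnt3 (ENSMUSG00000061723, chromosome 7, 142052573 to 142069746), which encodes the troponin T of fast skeletal muscle, averaged 23.1 ± 5.05 CPM (SD, n = 3) in floxed and 2.12 ± 0.251 CPM (SD, n = 3) in knockout hearts. It fell by 3.44 on the log2 scale, with a standard error of 0.25 and an adjusted p of 0.0192 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among the 16591 genes tested, 2 were therefore lower in the knockout and 0 were higher. At an unadjusted p under 0.05, edgeR placed 725 genes higher and 439 lower, against 830 expected by chance over both directions. DESeq2 called 123 genes higher and 120 lower on the same counts, whereas limma-voom called 1 gene, which was lower. The libraries of the 2 genotypes did not overlap for 965 genes higher and 992 genes lower in the knockout, 11.8% of the genes tested, where chance gives 10%. The number of calls depended on which libraries were used. The sizes did so less: over 17 settings Gsdmd had log2 fold changes of -6.34 to -5.96 and Tnnt3 of -3.59 to -2.71. Without knockout library 1 edgeR called 500 genes, 412 of them higher, Gsdmd and Tnnt3 both included, and without any 1 of the other 5 libraries it called 0, where Gsdmd had an adjusted p between 0.0724 and 0.166 and 545 to 1533 genes had an unadjusted p under 0.05.

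**Figure D1:**
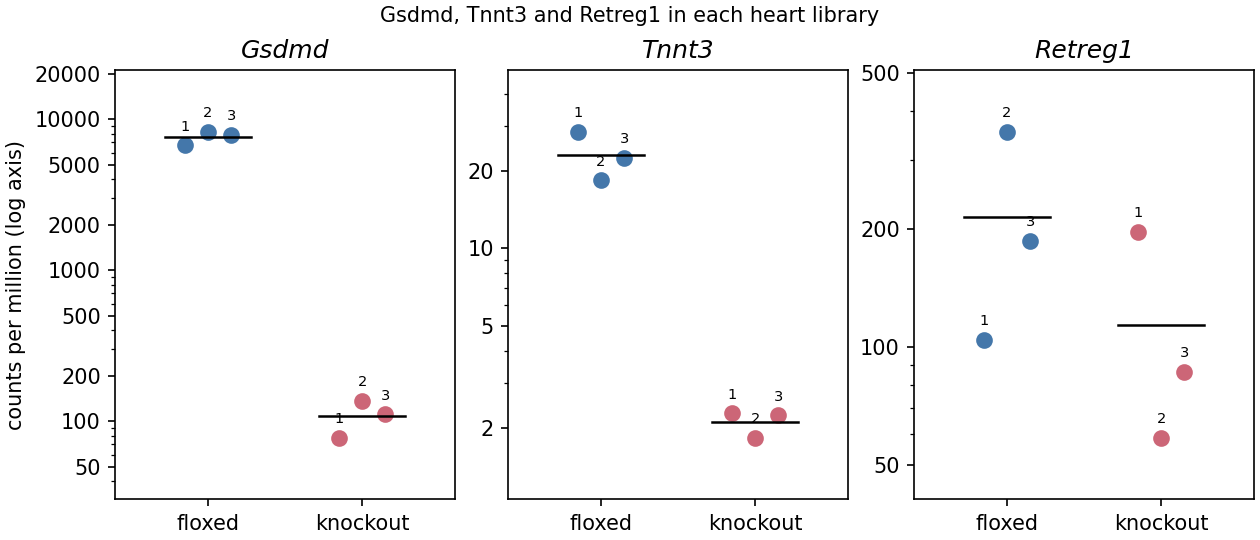
CPM (log axis) of Gsdmd, Tnnt3 and Retreg1 in each of the 3 floxed and 3 knockout heart libraries, with points numbered by replicate and lines at the group means. Gsdmd and Tnnt3 separate the genotypes with means of 7613 against 108 and 23.1 against 2.12, while the Retreg1 values overlap, with means of 215 against 114.

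Retreg1 (ENSMUSG00000022270, chromosome 15, 25843266 to 25973773, plus strand) encodes FAM134B, a receptor that delivers fragments of the ER to autophagosomes. Its level did not differ between the genotypes beyond the spread of the libraries. It measured 104, 354 and 186 CPM in the floxed libraries 1, 2 and 3 and 197, 58.6 and 86.4 CPM in the knockout libraries 1, 2 and 3. The log2 fold change was -0.92 with a standard error of 0.58, a 95% interval from -2.28 to 0.44 and an adjusted p of 0.854 in edgeR's quasi-likelihood test. Retreg1 is itself 1 of the 12 members of the ER-phagy list fixed before the data were examined, of which 9 had negative log2 fold changes, with a median of -0.17. The set test camera placed this list lower in the knockout at an adjusted p of 0.0485 with its preset correlation between genes, and the adjusted p was 0.542 with an estimated correlation. Tex264, another ER-phagy receptor, averaged 98.47 ± 11.04 CPM in floxed and 64.5 ± 1.61 CPM in knockout hearts (SD, n = 3), and Cdk5rap3, a component of the UFMylation machinery at the ER, 71.4 ± 1.61 and 56.0 ± 7.39 CPM. No member passed over all genes or when adjusted over the list alone. The list's call with the preset correlation also ended without floxed library 2 or 3 or without any 1 of the knockout libraries, where the adjusted p lay between 0.0516 and 0.153.

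The ER stress and unfolded protein response list was lower as a set with the preset correlation (camera adjusted p = 0.00385), although its median log2 fold change over 32 members was only -0.04 and its mean -0.21, with 17 members negative and 15 positive. With an estimated correlation the adjusted p was 0.618. Chac1, a glutathione-degrading enzyme induced in the integrated stress response, averaged 20.0 ± 4.11 CPM in floxed and 7.17 ± 2.05 CPM in knockout hearts (SD, n = 3). It did not pass over all genes (edgeR adjusted p = 0.529), and 1 member passed when adjusted over the list alone. Dnajb9, an ER co-chaperone, averaged 51.2 ± 6.18 and 30.3 ± 4.58 CPM. The call ended without knockout library 1, where the median was 0.15 and the adjusted p 0.989, and without floxed library 1 the median was also positive, at 0.0282, while the test still placed the list lower (adjusted p = 0.0338).

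Genes of the core autophagy machinery were lower as a set by a median log2 fold change of -0.14, with 26 of 32 members negative (camera adjusted p = 0.0033 with the preset correlation). The adjusted p was 0.542 with an estimated correlation, and 0 members passed over all genes or over the list alone. The autophagy receptor Sqstm1 averaged 968 ± 157 CPM in floxed and 576 ± 134 CPM in knockout hearts (SD, n = 3), with no overlap between the libraries. Gabarapl1, a homologue of LC3 on the autophagosome membrane, averaged 166 ± 44.7 and 99.4 ± 44.2 CPM, with overlap. The mitophagy list had a median of -0.14 over 10 members, -0.294 to -0.0801 without 1 library at a time, and did not pass with all libraries (adjusted p = 0.111), although it passed as lower without floxed library 1 (0.0408, and 0.444 with an estimated correlation), and its first members by p, Bnip3l and Mul1, had log2 fold changes of -0.26 each.

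The apoptosis list did not differ between the genotypes, with a median log2 fold change of -0.03 and a mean of 0.02 over 30 members (camera adjusted p = 0.941), the test pointing the way of the median. None of its members passed over all genes or over the list alone. Bbc3, which encodes the pro-apoptotic protein PUMA, averaged 42.5 ± 4.03 CPM in floxed and 30.04 ± 0.4042 CPM in knockout hearts, and Xiap, an inhibitor of caspases, 45.3 ± 3.33 and 63.7 ± 4.75 CPM (SD, n = 3), neither with overlap between the libraries. Of the pyroptosis and inflammasome list, Gsdmd itself was the single member of 19 that passed, both over all genes and over the list alone. As a set this list, with Gsdmd included, did not pass (median 0.40, mean 0.03, camera adjusted p = 0.725). The targeted gene, at a log2 fold change of -6.13, lowers the mean, and the list was not tested without it. Without knockout library 1 it passed as higher (median 0.68, adjusted p = 0.0288, and 0.585 with an estimated correlation), and without floxed library 2, knockout library 2 or knockout library 3 the test pointed down, short of the threshold, at medians of 0.22, 0.16 and 0.27.

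Across all lists fixed before the data were examined, 34 had at least 5 tested members, and with the preset correlation 21 of these passed in camera, 5 higher and 16 lower in the knockout. With an estimated correlation 0 of the 34 passed, the lowest adjusted p being 0.122 and 4 lists having an unadjusted p under 0.05, and by fry, which tests whether the genes of a list move one way, 1 list passed. Without each library in turn, 8 of the 21 lists still passed with the preset correlation, namely those of core autophagy, p53 targets, oxidative stress, cardiac stress, fatty acid oxidation, cell division, T and NK cells and skeletal muscle. Their sizes moved more than their calls, and the medians spanned -1.16 to -0.33 for fatty acid oxidation, -1.05 to -0.37 for skeletal muscle, -0.46 to -0.26 for oxidative stress and -0.24 to -0.10 for core autophagy.

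**Figure D2:**
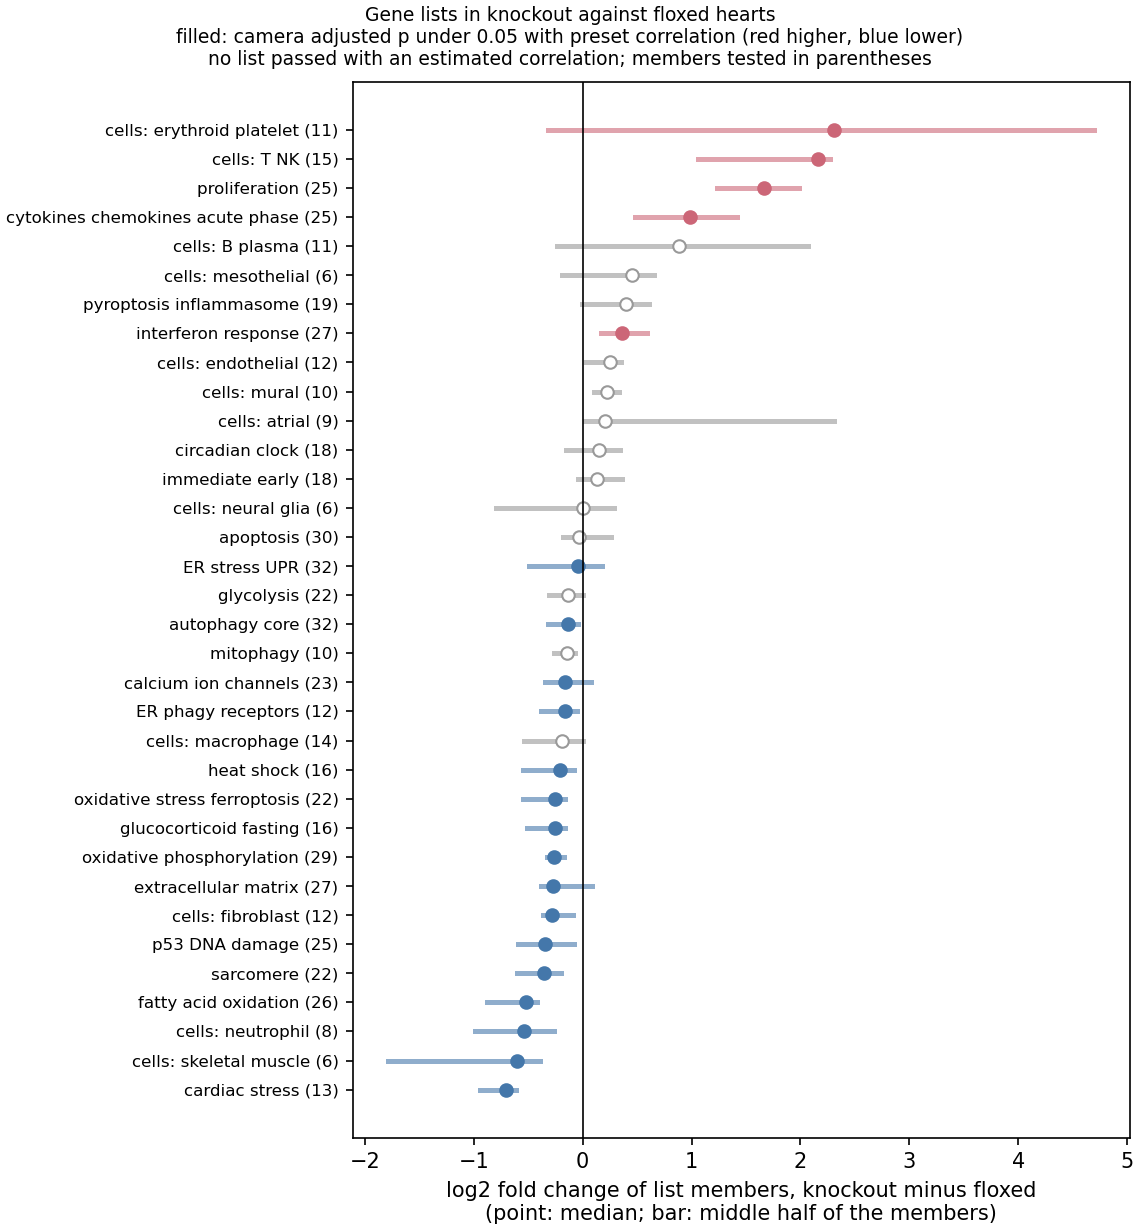
Median log2 fold change, knockout minus floxed, of the tested members of each of the 34 gene lists on the horizontal axis, with bars over the interquartile range of the members and the number of members in parentheses. Filled points mark the 5 lists higher and the 16 lists lower at a camera adjusted p under 0.05 with the preset correlation, from a median of 2.31 for erythroid and platelet genes, which was 0.29 without knockout library 3, to -0.70 for cardiac stress genes. None passed with an estimated correlation.

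Taken as lists, genes of cardiac stress, p53 targets and genes of oxidative stress had lower levels in each knockout library than in any floxed library. So did the skeletal muscle list, at -0.76, -0.71 and -1.40 in knockout libraries 1, 2 and 3 against -0.26 to 0.21 in the floxed libraries. The neutrophil list also did, at -0.51, -0.27 and -0.69 against -0.22 to 0.49. Chance separates the genotypes, in either direction, for 10% of single values, so some of the lists may separate by chance. The median level of the heat shock list was lower mainly in knockout library 1, at -0.84 against -0.10 and -0.01 in knockout libraries 2 and 3 and -0.05 to 0.07 in the floxed libraries. Single members differed from this: 5 of 16 were lower, and 0 higher, in every knockout library than in any floxed library. Among the 5 was Hspb1, at 501 to 574 CPM in the knockout and 1527 to 1608 CPM in the floxed libraries. The cardiac stress list had a median log2 fold change of -0.70, with 12 of 13 members negative and 4 members lower when adjusted over the list alone (camera adjusted p = 1.24e-07 with the preset correlation, 0.122 with an estimated correlation). Nppa, which encodes atrial natriuretic peptide, averaged 1358 ± 182 CPM in floxed and 392 ± 188 CPM in knockout hearts, and Ankrd1, a stretch-responsive protein of the sarcomere, 2303 ± 257 and 1277 ± 44.0 CPM (SD, n = 3). Neither passed over all genes, with edgeR adjusted p-values of 0.529 and 0.546. Targets of p53 had a median of -0.35, with 20 of 25 members negative and 2 members lower over the list alone (adjusted p = 4.68e-06 with the preset correlation, 0.275 with an estimated correlation). Plk2 averaged 131 ± 13.8 and 73.1 ± 4.93 CPM and Gadd45a, a growth arrest and DNA damage gene, 23.1 ± 4.37 and 10.6 ± 2.01 CPM. The heat shock list had a median of -0.21, with 12 of 16 members negative and 4 lower over the list alone (adjusted p = 2.42e-04 with the preset correlation, 0.542 with an estimated correlation). The small heat shock protein gene Hspb1 averaged 1579 ± 44.7 CPM in floxed and 544 ± 38.4 CPM in knockout hearts with an edgeR adjusted p of 0.221, and Hspb8 684 ± 37.6 and 317 ± 82.5 CPM. The heat shock list no longer passed without knockout library 1 (median -0.0754, adjusted p = 0.236). The oxidative stress and ferroptosis list had a median of -0.25, with 18 of 22 members negative (adjusted p = 6e-04 with the preset correlation, 0.333 with an estimated correlation). Of its members, Srxn1, which reduces oxidised peroxiredoxins, averaged 147 ± 15.1 and 60.6 ± 34.2 CPM and Cat, the gene for catalase, 151 ± 32.9 and 102 ± 21.8 CPM.

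Contractile and metabolic genes of heart muscle were also lower as lists, but their levels in the libraries of the 2 genotypes overlapped. The sarcomere list had a median log2 fold change of -0.35 with 19 of 22 members negative (camera adjusted p = 2.33e-05 with the preset correlation, 0.575 with an estimated correlation, and 0.0775 without knockout library 3). Des, which encodes the intermediate filament desmin, averaged 3104 ± 283 CPM in floxed and 1605 ± 278 CPM in knockout hearts, and Csrp3, which encodes muscle LIM protein, 1060 ± 151 and 586 ± 112 CPM (SD, n = 3). Fatty acid oxidation genes had a median of -0.52 with 25 of 26 members negative (adjusted p = 2.45e-06 and, with an estimated correlation, 0.575). Their level was 0.22 in knockout library 1 and -0.88 and -1.13 in knockout libraries 2 and 3, against -0.61, 0.57 and 0.04 in the floxed libraries. Among them were the lipid droplet gene Plin2 with 265 ± 68.5 and 130 ± 7.32 CPM and Cpt2 with 74.4 ± 14.5 and 54.3 ± 10.4 CPM. Oxidative phosphorylation genes had a median of -0.26, with 29 of 29 members negative (adjusted p = 0.00154 and, with an estimated correlation, 0.686), Cox5a averaging 237 ± 76.8 and 176 ± 1.63 CPM. This call ended without floxed library 2 (adjusted p = 0.459) or knockout library 3 (0.252), as did that of the calcium and ion channel list (0.587 and 0.418), whose median was -0.16 over 23 members (adjusted p = 0.0233 and, with an estimated correlation, 0.618). Casq2, the calcium-binding protein of the sarcoplasmic reticulum, averaged 239 ± 13.9 and 135 ± 26.2 CPM. The glucocorticoid and fasting list had a median of -0.26 over 16 members (adjusted p = 0.0183 and, with an estimated correlation, 0.686). This call ended without floxed library 2 or 3 or knockout library 2 or 3, where the adjusted p lay between 0.135 and 0.375. Without 1 library at a time the medians spanned -0.77 to -0.12 for the sarcomere, -0.511 to -0.0411 for the oxidative phosphorylation, -0.468 to 0.0491 for the calcium and -0.802 to -0.00424 for the glucocorticoid list, each lowest without knockout library 1. The glycolysis list did not pass with all libraries (median -0.13 over 22 members, -0.230 to -0.0439 without 1 library at a time, adjusted p = 0.0608) and passed as lower without floxed library 1 (0.0206, and 0.422 with an estimated correlation). Gapdh averaged 103 ± 69.0 and 22.9 ± 5.45 CPM, a level that is uncertain because the gene has many near-identical processed pseudogenes. No member of these 6 lists passed over all genes or over the list alone.

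Transcripts of T and NK cells and of dividing cells were higher in knockout libraries 2 and 3, taken as lists. In knockout library 1 they lay within the range of the floxed libraries. The T and NK cell list had a median log2 fold change of 2.16 with 13 of 15 members positive. Of these, 9 were higher when adjusted over the list alone while 0 passed over all genes (camera adjusted p = 1.08e-05 with the preset correlation, 0.575 with an estimated correlation). Cd8a, a coreceptor of cytotoxic T cells, measured 26.4, 13.0 and 19.5 CPM in the floxed libraries 1, 2 and 3 and 31.2, 142.7 and 148.7 CPM in the knockout libraries 1, 2 and 3. Trac, the constant chain of the T cell receptor alpha, averaged 10.6 ± 4.77 and 53.9 ± 32.2 CPM (SD, n = 3). The cell division list had a median of 1.66 with 25 of 25 members positive and 0 past the threshold over all genes or over the list alone (adjusted p = 1.2e-09 with the preset correlation, 0.575 with an estimated correlation). Plk1, a mitotic kinase, averaged 3.26 ± 0.550 and 12.5 ± 6.65 CPM, and Bub1, a kinase of the spindle checkpoint, 1.503 ± 0.6788 and 7.12 ± 4.30 CPM. The cytokine, chemokine and acute phase list had a median of 0.98 over 25 members (adjusted p = 2.59e-04 with the preset correlation, 0.590 with an estimated correlation, and 0.0595 without knockout library 3). Its member Ccl5, a chemokine that T cells secrete, averaged 65.0 ± 26.9 and 234 ± 133 CPM and the acute phase gene Saa3 4.45 ± 2.09 and 17.6 ± 9.69 CPM. The interferon response list had a median of 0.36 over 27 members (adjusted p = 0.015 with the preset correlation, 0.719 with an estimated correlation), Gbp3 averaging 119 ± 19.4 and 253 ± 124 CPM. This call ended without floxed library 2 (adjusted p = 0.459), knockout library 2 (0.863, at a median of 0.0356) or knockout library 3 (0.0959). The B and plasma cell list did not pass with all libraries (median 0.89 over 11 members, adjusted p = 0.123), Ighm averaging 22.6 ± 10.7 and 97.6 ± 64.3 CPM. It passed as higher without floxed library 1 (median 1.39, adjusted p = 0.0042, and 0.444 with an estimated correlation) or knockout library 1 (1.203, 0.0321 and 0.594). Its median was 0.22 without knockout library 2.

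The erythroid and platelet list had a median log2 fold change of 2.31 over 11 members, 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0183 with the preset correlation, 0.542 with an estimated correlation). Its members went both ways, 7 positive and 4 negative, and without knockout library 3 the median was 0.29 and the adjusted p 0.0562. The median level of the list was 0.22, 0.37 and 3.46 in knockout libraries 1, 2 and 3 against at most 0.30 in the floxed libraries. The globin gene Hbb-bs measured 2.29, 4.32 and 6.20 CPM in the floxed libraries and 26.4, 170.3 and 204 CPM in the knockout libraries 1, 2 and 3, so the globin was high in knockout library 2 as well, and Hba-a1 averaged 5.67 ± 2.66 and 105 ± 74.7 CPM (SD, n = 3). Neither passed over all genes (edgeR adjusted p of 0.438 and 0.529), and both have near-identical copies among the globin genes that can share their reads.

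**Figure D3:**
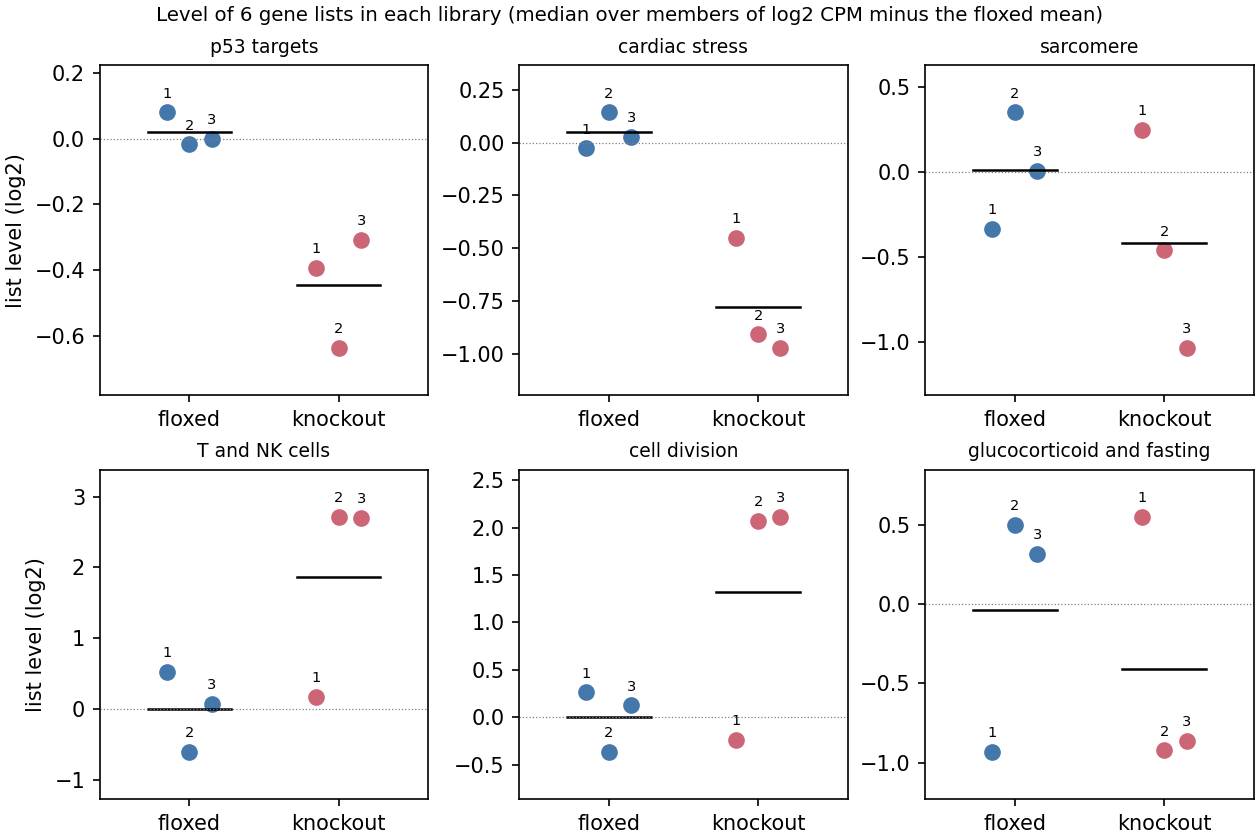
Level of 6 gene lists in each library (vertical axis, the median over members of log2 CPM minus the mean of the floxed libraries; points numbered by replicate, lines at the group means). The p53 target and cardiac stress lists lie between -0.64 and -0.31 and between -0.97 and -0.45 in the 3 knockout libraries, below every floxed library, while T and NK cell and cell division genes stand above the floxed libraries in knockout libraries 2 and 3, at 2.70 to 2.72 and 2.08 to 2.12.

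The skeletal muscle list, of which 6 of 12 genes could be tested, had a median of -0.60 and all 6 negative, with 1 member, Tnnt3, past the threshold over all genes and 3 lower over the list alone (camera adjusted p = 2.7e-05 with the preset correlation, 0.164 with an estimated correlation), and it was the list that passed by fry (adjusted p = 0.041). Some of its members, such as Acta1 and Ckm, are also transcribed in heart muscle. The neutrophil list had a median of -0.54 over 8 members (adjusted p = 0.044 and, with an estimated correlation, 0.575), the fibroblast list -0.28 over 12 members (0.0445 and 0.575) and the extracellular matrix list -0.27 over 27 members (0.0366 and 0.764). Spp1, which encodes osteopontin, averaged 363 ± 65.7 and 144 ± 88.8 CPM (SD, n = 3). The call of the neutrophil list ended without floxed library 3 or knockout library 1 or 3 (adjusted p of 0.143 to 0.257), and those of the fibroblast and matrix lists without floxed library 1 or 3 or knockout library 1 or 2 (0.116 to 0.303 and 0.0952 to 0.989). Without 1 library at a time their medians spanned -0.816 to -0.229, -0.564 to -0.0726 and -0.834 to 0.0353. With all libraries no list passed among the macrophage (median -0.19, adjusted p = 0.0532), endothelial (0.25, 0.941, with a test that pointed down), mural (0.22, 0.570), mesothelial (0.45, 0.995) and neural and glial genes (0.00, 0.377, with a mean of -0.27). The macrophage list passed as lower without floxed library 2 (median -0.43, adjusted p = 0.00209, and 0.773 with an estimated correlation), knockout library 2 (-0.41, 0.00427 and 0.699) or knockout library 3 (-0.33, 0.0217 and 0.696). Its median was 0.0922 without knockout library 1. The endothelial list passed as lower without knockout library 1 (-0.27, 0.0428 and 0.679) and as higher without knockout library 3 (0.64, 5.54e-04 and 0.622). The medians of the mural, mesothelial and neural lists then spanned 0.0715 to 0.381, -0.300 to 1.01 and -0.288 to 0.0345. Trem2, a receptor of lipid-handling macrophages, averaged 235 ± 72.6 and 109 ± 35.9 CPM, and the mesothelial list held 1 member higher and 1 lower when adjusted over the list alone. These were Upk3b, a uroplakin, at 0.0763 ± 0.0663 and 1.83 ± 1.55 CPM, and Krt19, an epithelial keratin, at 4.64 ± 0.928 and 0.686 ± 0.209 CPM. The atrial list did not pass with all libraries (median 0.21, 0.0948 to 0.723 without 1 library at a time, adjusted p = 0.643) and passed as higher without knockout library 3 (0.55, 0.0397, and 0.622 with an estimated correlation). The atrial myosin light chain Myl7 measured 75.1 CPM in knockout library 1 and 5.18 and 0.0998 CPM in knockout libraries 2 and 3, against 0.240 to 0.598 CPM in the floxed libraries. The circadian (median 0.15, adjusted p = 0.941) and immediate early lists (0.13, 0.643) did not pass with all libraries. Their medians spanned -0.0326 to 0.226 and -0.106 to 0.290 without 1 library. The immediate early list passed as higher without knockout library 1 (adjusted p = 0.00532, and 0.391 with an estimated correlation). The adipocyte, lung and sex-linked lists had 2, 3 and 4 tested members and were not tested as sets, and their medians were -0.10, -0.35 and 0.31.

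The deposited table annotates genes with Gene Ontology (GO) terms, and 2128 of these held 10 to 500 tested genes. Among the 2 genes lower in the knockout, 0 terms were enriched in a one-sided Fisher exact test, 22 terms having an unadjusted p under 0.05 and the lowest adjusted p being 0.586, and the 0 genes higher gave nothing to test. With 2 genes the test could hardly call a term unless it held both. A term of 10 genes, the smallest size tested, that held 1 of them had an unadjusted Fisher p of 0.00121.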

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

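Library size without mitochondrially encoded genes and Gsdmd, edgeR without robust estimation and camera over GO terms were chosen after seeing the data. Gsdmd stayed past the threshold with RLE, with no filter or a filter on CPM, with DESeq2, limma-voom and the 3 FPKM settings, and with both added edgeR settings, and Retreg1 stayed short of it in all 17 settings, at log2 fold changes from -1.58 to -0.36. The number of genes changed was 10 with no filter on low counts, all 10 lower, 243 with DESeq2 (123 higher, 120 lower) and 1 with limma-voom, which was lower. Leaving out 1 library at a time gave 0 to 500 genes changed, 0 to 412 higher and 0 to 88 lower. Gsdmd then had log2 fold changes of -6.34 to -5.96 and kept its call without knockout library 1 only. With the replicate number as a block, 0 genes were changed and 0 lower, at 509 genes with an unadjusted p under 0.05, and Gsdmd had a log2 fold change of -6.17 at an adjusted p of 0.343. Deviations from the genotype means of same-numbered libraries correlated across genes at -0.57, -0.31 and 0.04, which gave no sign of a pairing by number. These correlations cannot exclude one, because deviations from a mean of few libraries are tied to one another.

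The number of lists past the threshold was 0 with an estimated correlation and 1 by fry, against 15 to 22 without 1 library. ER stress (median -0.0424), ER-phagy (-0.17) and autophagy genes (-0.14) lost their calls with an estimated correlation or by fry, settings that cannot alter the medians. ER-phagy genes (-0.18) also lost theirs with the block, with which macrophage genes passed as lower (camera adjusted p = 0.0494 with the preset correlation, against 0.686 with an estimated correlation and no block). Without 1 library at a time the medians of ER stress, ER-phagy and autophagy genes spanned -0.25 to 0.15, -0.195 to -0.0896 and -0.24 to -0.10, and that of apoptosis genes -0.0497 to 0.0167. Matrix genes then spanned -0.834 to 0.0353, with the direction turned without knockout library 1. Interferon genes spanned 0.0356 to 0.531, with the direction of the test turned without knockout library 2, and endothelial genes -0.271 to 0.639, past the threshold as lower without knockout library 1 and as higher without knockout library 3. Camera over GO terms, with 2128 terms, called 108 with the preset correlation and 0 with an estimated one. The Fisher test called 0, but with 2 genes to place it could hardly call any. Of 330 values of other lists under the alternatives, 237 kept direction and side of the threshold, and of 1166 values of other named genes, 1118 did. These other genes, Tnnt3 apart, were short of the threshold in the main test, so keeping their side mostly meant staying uncalled. In simulated counts of this depth and spread, changes of 1 on the log2 scale were mostly not detectable. In the hearts larger differences also went uncalled, such as Hbb-bs at a log2 fold change of 4.97 (edgeR adjusted p = 0.438) and Cd8a at 2.45 (0.529). The absence of a call therefore does not exclude a large change.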

Other observations

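The genes and terms in this paragraph were chosen after their values were seen. Close behind Gsdmd and Tnnt3, 11 more genes had an adjusted p under 0.25 in edgeR's quasi-likelihood test, and all 11 were lower in the knockout without overlap between the libraries. Gpnmb averaged 198.6 ± 28.7 CPM in floxed and 56.7 ± 11.1 CPM in knockout hearts, the vacuolar ATPase subunit Atp6v0d2 13.5 ± 3.49 and 2.14 ± 0.806 CPM and the macrophage elastase Mmp12 27.9 ± 3.98 and 5.41 ± 2.30 CPM (SD, n = 3). Nes, which encodes the intermediate filament nestin, averaged 304 ± 65.4 and 79.0 ± 18.1 CPM. The gene 2210017I01Rik was close to absent from the knockout libraries, at 5.35, 8.52 and 10.8 CPM in the floxed libraries and 0.0635, 0 and 0 CPM in the knockout libraries, with an adjusted p of 0.0562. The macrophage list did not pass with all 6 libraries (adjusted p = 0.0532). Over GO terms, camera with the preset correlation placed 75 terms higher and 33 lower, and with an estimated correlation 0 passed. The first terms higher were the centromeric region of chromosomes (120 genes, median log2 fold change 0.33, adjusted p = 1.27e-06 and 0.874 with an estimated correlation) and DNA replication (107 genes, 0.32, 1.23e-05 and 0.874), and the first lower was sarcomere organization (24 genes, -0.24, 1.03e-04 and 0.874).

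Of the tests that follow, the splits of the libraries and the test of the region around Gsdmd were set before their results were seen, and the others after. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2 genes changed and the highest of the others 370, with 2 of the 10 splits giving at least 2. For genes lower, 2 of the 10 splits gave at least the real 2, the highest other giving 208 in one direction, and for genes higher the real count was 0, which 10 of 10 splits reached, with a highest other of 208. For lists past the threshold with the preset correlation the real split gave 21, which 1 split reached, itself, and the highest other gave 19. The split with 370 genes set floxed library 1 and knockout libraries 2 and 3 against the rest, so the libraries hold a structure that does not follow genotype. The first principal component, with 53.6% of the variance, places floxed 1 and knockout 2 and 3 on one side (-15.6, -43.2 and -72.3) and the others on the other (50.6, 17.9 and 62.6). The glucocorticoid and fasting list differs in the same way, at -0.93, 0.50 and 0.32 in floxed libraries 1, 2 and 3 and 0.55, -0.92 and -0.86 in knockout libraries 1, 2 and 3. The second component, with 21.8% of the variance, separates the genotypes. It places floxed libraries 1, 2 and 3 at -29.5, -18.1 and -32.8 and knockout libraries 1, 2 and 3 at 41.9, 41.4 and -2.87.

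A first pattern is the level of Gsdmd in the floxed libraries, where it is among the most abundant transcripts. A swap of a library between the genotypes is excluded, because the highest knockout library reaches 2.04% of the lowest floxed one. This test cannot show whether the floxed hearts as a group carried more than their label states. Higher transcription of the whole region is argued against by the 32 tested genes within 500 kb, whose median log2 fold change is -0.0396 with a standard error of 0.0473, taken across these genes and not across libraries. A Gsdmd sequence added from outside the locus, which could supply 0.756% of the reads, and a strong response of the gene itself to doxorubicin cannot be told apart, since counts per gene hold no positions within the transcript and no hearts without doxorubicin were analysed here. The 70.2-fold difference is therefore a difference from this unusually high level.

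A second pattern is that T cell and division genes are high in knockout libraries 2 and 3 and not in knockout library 1, so the genotype alone did not produce it in each library. Residual blood cannot be told apart. Summed globin transcripts stand at 343 and 403 CPM in these libraries against at most 14.7 CPM in the floxed libraries, which goes with blood. They stand at 48.7 CPM in knockout library 1, also above the floxed libraries although it lacks the pattern. In knockout libraries 2 and 3 they reach up to 0.374 times the summed CPM of the T and NK cell list, a ratio whose value in blood these tables do not hold. The neutrophil transcripts S100a8 and S100a9 go the other way, at 3.61 and 2.15 CPM and 5.445 and 1.298 CPM in knockout libraries 2 and 3 against 3.95 to 7.34 and 5.64 to 8.05 CPM in the floxed libraries. These levels are low, and those of knockout library 2 lie only just below the lowest floxed library. Less doxorubicin exposure of these mice, which might spare dividing cells, cannot be told apart from other causes: the p53 target genes of knockout library 1 differ from the mean of libraries 2 and 3 by a median of -0.00328 on the log2 scale with a standard error of 0.225. This standard error is taken across the 25 genes and does not measure the spread between libraries. An infiltrate of dividing T cells remains a hypothesis that these tables do not test.

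A further pattern is that cardiac stress and p53 target lists are low in all 3 knockout libraries. Fewer cardiomyocytes in the knockout libraries would raise the markers of every other cell type, but the fibroblast list has a median of -0.28 and the endothelial list one of 0.25, and neither is resolved from the spread between libraries with an estimated correlation, so this cannot be told apart for the group as a whole. In knockout library 1 the sarcomere, fatty acid oxidation and oxidative phosphorylation lists stand at 0.25, 0.22 and 0.23, within the floxed range, while its cardiac stress and p53 levels are -0.45 and -0.39, and values of 1 library decide nothing for the group. In knockout libraries 2 and 3 the sarcomere list stands at -0.46 and -1.04 and the fatty acid oxidation list at -0.88 and -1.13. These lie below the lowest floxed levels of -0.33 and -0.61, which goes with fewer cardiomyocytes in these libraries. The oxidative phosphorylation list stands at -0.37 and -0.60 there, against a lowest floxed level of -0.41. Less doxorubicin damage through lower exposure would lower p53 targets and spare dividing cells, and 2 of the 3 knockout libraries show both. Exposure is not recorded in the labels and is confounded with genotype, so a lower exposure and a protection by the knockout itself may each account for the pattern and cannot be told apart here. Without hearts that had no doxorubicin, a difference between the genotypes unrelated to the drug cannot be told apart either.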
